A study of Mus musculus with 27 samples.

How the data were processed

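The series holds 27 mouse samples of 3 kinds. Long RNA was sequenced in 18 libraries of testicular cells sorted by DNA content, which the labels call 1n (spermatids) and 4n (spermatocytes), from wild type (WT) animals and from the knock-in lines Strep1 and Strep2, with 3 libraries per genotype and population. Small RNA was sequenced in 5 libraries from Strep-tagged MIWI purified from Strep1 testes. The products of an in vitro slicing assay were sequenced in 4 libraries, 2 for each of 2 pools of artificial target RNA. MIWI is the protein of the gene Piwil1, a PIWI-clade Argonaute that binds piRNAs. Groups came from the titles and characteristics in the labels. The genotype labels name the strains RP68 for Strep1 and RP85 for Strep2, while the growth protocol names RP85 and RP86, so which strain and tag position belongs to which line is open, and values are assigned by the genotype label. Nothing in the labels says which libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical in part.

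The long RNA and small RNA tables were deposited as RPM (reads set against a library total), separately for the sense and the antisense strand, over Ensembl genes, tRNAs, pachytene piRNA clusters and repeat subfamilies. Per the submitters' processing notes, cutadapt, Bowtie, STAR, featureCounts, Salmon 1.3.0, DESeq and DESeq2 were used with the build GRCm39, with no statement of which tool made which table. The denominator of the deposited RPM values is not stated. The slicing table was deposited as RPM summed over all targets of a pool for each strand, read start and read end, and per the labels reads were mapped to the pool sequences. A further table per line and population was deposited with normalized signal per library, from Salmon per its name, with the authors' log2 fold changes and their p-values and adjusted p-values. The small RNA tables held 4 further columns of values, 2 in each, that belong to no sample of the labels, and these were not used.

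The RPM values could not be turned back into reads. Taking the commonest low value of a library as 1 read, 41.3% to 45.2% of the non-zero gene values were within 0.01 of a whole number of reads, and 50.2% to 52.7% of those under 20 reads, because reads were counted in fractions. A count model, which had been planned before the data were examined, therefore did not suit the values, and no edgeR or DESeq2 test was run here. The value of 1 read put the depth at 33 to 63.21 M reads for the long RNA libraries and at 12.03 to 20.75 M for the small RNA libraries. The depth of the slicing libraries is unknown. The planned binomial intervals on shares need read counts and were not computed.

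Long RNA was tested with limma 3.58.1 (linear models with moderated variance, trend on) in R 4.3.3 on log2(RPM + 0.1), with tables read by the data.table package (1.17.8). Features with at least 0.3 RPM in at least 3 libraries of a fit were kept. Libraries were scaled by a trimmed mean of log ratios against the mean library, with 30% of the ratios and 5% of the levels trimmed from each end. The 9 libraries of a population were fitted together for the comparisons of genotypes, and all 18 libraries for the comparisons of 1n with 4n cells and for the test of whether a line's difference from WT itself differed between populations. Benjamini-Hochberg adjustment at a false discovery rate (FDR) of 0.05 was made over genes, over repeats and over piRNA clusters separately. A log2 fold change is on the log2(RPM + 0.1) scale and understates the change of low genes. The tests of piRNA clusters were added after the tables were seen. Sums of RPM and slicing values were compared by exact two-sided permutation tests, whose smallest possible p is 0.1 for 3 against 3 libraries and 0.33 for 2 against 2.

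The library names give 2 library series. The 1n WT and 1n Strep2 libraries are of one series, and the 1n Strep1 and all 4n libraries of the other. The comparisons within 4n cells, 1n Strep2 against WT and Strep1 1n against 4n lie within one series. The comparisons of 1n Strep1 with WT or Strep2, and of 1n with 4n cells in WT and Strep2, coincide with a change of series, and no value within a series can be given for them. The nearest values within one series are those of Strep1 for 1n against 4n cells and those of 4n cells for Strep1 against WT, and they are given beside the results.

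On simulated values for 1n Strep1 against WT over 20632 genes, the procedure recovered 72 of 100 genes changed 2-fold and 94 of 100 changed 4-fold, with 9 false calls. For 4n Strep1 against WT over 18139 genes it recovered 61 and 92 of 100, with 6 false calls. An unchanged comparison gave 0 calls in both. In the simulation each gene varied independently of the others. Differences between libraries that many genes share were not simulated, so real false calls may be more. Pearson correlations across genes between libraries of a group were 0.992 to 0.996, and genes are not independent replicates.

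Before the data were examined, 14 gene lists and the rule for naming genes were fixed. Named are Piwil1, up to 6 genes with the largest fold in each direction among called genes whose groups do not overlap, of sufficient level and with an established symbol, the largest of any name, up to 3 or 4 members of each list with the smallest p, the 5 repeats of smallest p, the 10 strongest small RNA features and the 3 strongest slicing positions. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 56 tests of lines against WT or over the 14 lists. The lists were the piRNA pathway, meiotic prophase, round spermatid and acrosome, elongating spermatid and sperm tail, spermatogonia, Sertoli cell, Leydig cell, peritubular myoid and endothelial, macrophage and blood, p53 and DNA damage response, heat shock and immediate early, interferon response, sex chromosome genes silenced in pachytene, and mitochondrially encoded genes. One member of the sex chromosome list, H2bl1, lies on chromosome 13 in the annotation.

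Gene coordinates are those of GENCODE vM39 on GRCm39, matched by Ensembl identifier. Of 54748 matched genes, 54711 had the same chromosome in the deposited table and the annotation. In the slicing table position 0 was taken to lie opposite the first piRNA base, so that the product of a cut opposite piRNA bases 10 and 11 starts at position -9. This reading was inferred from the strand and positions of the reads. Agreement of the small RNA libraries was planned across genes and is also given across genes, repeats and clusters. Alternatives covered the pseudocount, the filter, the scaling, the libraries in the fit, the replicate number as a block, each library left out in turn and the deposited Salmon values. Labels were read with jsonlite 2.0.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.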

Results

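The study profiled RNA in sorted male germ cells of WT mice and of the lines Strep1 and Strep2, in which MIWI carries a Strep tag, to see whether genes and repeats are expressed alike. It also profiled the small RNA bound to the purified tagged protein and the products that this protein makes from artificial targets. The long RNA libraries held an estimated 33 to 63.21 M reads, with group means from 40.5 ± 1.17 M (SD, n = 3) in 4n Strep1 to 52.4 ± 9.50 M (SD, n = 3) in 4n WT. Annotated genes took 570980 to 794300 RPM of a library.

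Spermatids (1n) and spermatocytes (4n) of WT mice differed in most of their genes. The protamines and transition proteins that package sperm DNA were far higher in 1n cells. Prm1 stood at 1498 ± 572 RPM in 1n against 29.1 ± 4.51 in 4n cells (SD, n = 3), and Tnp2 at 938 ± 298 against 19.7 ± 3.46. The testis-specific histones H1f6 and H2bc1 went the other way, H1f6 from 302.4 ± 33.03 RPM in 4n to 4.39 ± 0.874 in 1n cells. In the limma fit 18857 of 22824 genes were called, 9796 higher and 9061 lower in 1n cells, and 13551 changed at least 2-fold. Prm2, Tnp1, Cstl1 and Oxct2a completed the largest rises, with log2 fold changes from 5.06 to 5.22, and Pou5f2, Dhdh, Cenpo and Ccdc142 the largest falls, from -5.21 to -5.60. Strep1, whose libraries of both populations belong to one series, gave 18914 called genes, and Strep2 gave 19027. Populations coincide with series in WT and Strep2.

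Among the lists for late stages, 29 of 31 measured genes of elongating spermatids and the sperm tail rose in WT 1n cells, with a median log2 fold change of 4.03, and 29 of 31 rose in Strep1, within one series, with a median of 4.29. Akap4, a scaffold of the sperm tail, rose from 41.2 ± 11.9 to 856 ± 119 RPM, and Fscn3 by a log2 fold change of 4.87. Of 32 round spermatid and acrosome genes 26 rose and 1 fell, among them Ace (log2 fold change 3.09) and Tssk6 (4.59), while Tex101 was the member that fell (-3.14). Of 22 measured genes of the list for sex chromosome silencing 21 rose, with Cypt3 at a log2 fold change of 4.00 and H2bl1, on chromosome 13, at 4.16. Meiotic prophase genes were mixed, with 19 of 34 lower and 9 higher in 1n cells. Sycp2, a part of the synaptonemal complex, fell from 418 ± 16.9 to 107 ± 13.3 RPM, and Mlh3, a mismatch repair protein of crossovers, fell by 3.36 on the log2 scale.

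Of 28 measured piRNA pathway genes 18 fell and 6 rose in 1n cells. Piwil1 itself fell from 640 ± 76.1 to 35.8 ± 7.23 RPM, with a log2 fold change of -4.36 and a standard error (SE) of 0.13 (limma, adjusted p = 1.34e-15), Tdrd5 by 4.65 and Tdrd1 by 3.61 on the log2 scale. In Strep1, within one series, Piwil1 stood at 747 ± 50.6 RPM in 4n and 29.8 ± 2.65 in 1n cells. Of the 15 mitochondrially encoded genes 14 fell, with a median of -2.12. Of lists for other testis cells, that of macrophages and blood was called higher in 1n libraries by camera (8 of 9 rose, adjusted p = 0.0225, and adjusted p = 0.505 with an estimated correlation), and those of peritubular, Leydig and Sertoli cells were not (adjusted p = 0.125, 0.60 and 0.702). Of the peritubular and endothelial list 9 of 13 rose and 2 fell, of the Leydig list 3 of 6 rose and 2 fell, and of the Sertoli list 4 of 16 rose, 2 fell and 10 were not called. Called members stood at different levels, with Adgre1 at 3.75 ± 0.290 against 0.495 ± 0.0787 RPM, Vwf at 12.4 ± 2.23 against 1.98 ± 0.732, Scarb1 of the Leydig list at 46.5 ± 6.39 against 15.8 ± 1.61 and Tjp1 of the Sertoli list at 120.6 ± 3.80 against 52.05 ± 3.32 RPM. Of spermatogonial genes 9 of 18 rose and 4 fell, of heat shock and immediate early genes 11 of 20 rose and 7 fell, of p53 genes 5 of 16 rose and 9 fell, and of interferon genes 3 of 10 rose and 6 fell. Adjusted over the list alone these WT counts were the same in all 14 lists. With the preset correlation camera called 7 of the 14 lists, namely both spermatid lists, the sex chromosome, mitochondrial, piRNA pathway, meiotic and macrophage lists, with adjusted p from 3.07e-08 to 0.0225. None was called with an estimated correlation, where the smallest adjusted p was 0.505 with an estimated correlation, and fry called 13.

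**Figure D1:**
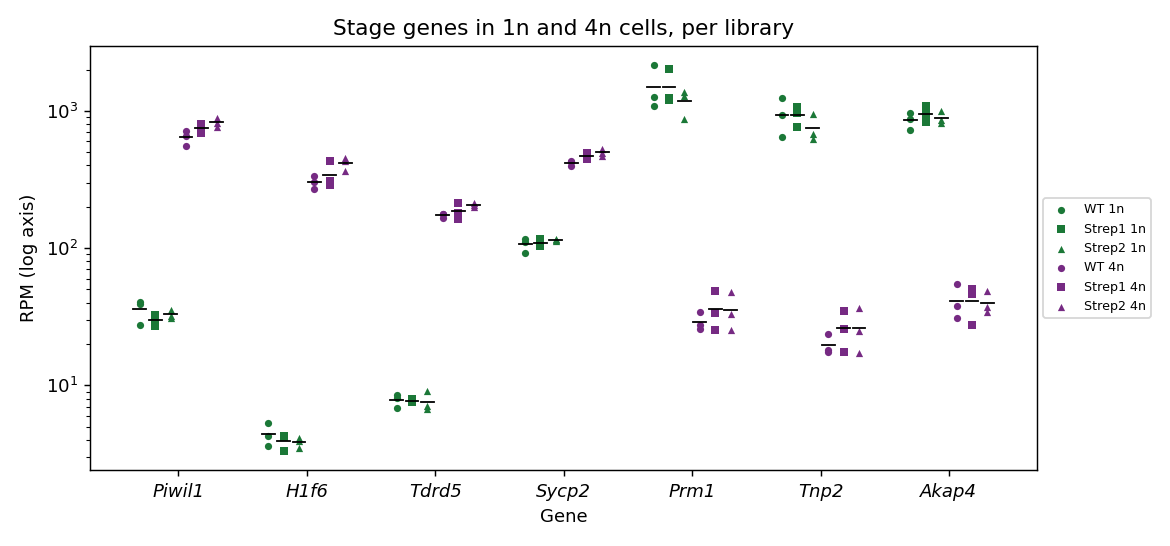
RPM (log axis) of 7 stage genes in each of the 18 long RNA libraries. Points are libraries, black lines are means of 3 libraries, green marks 1n and purple 4n cells, and shapes mark the genotype. Piwil1, H1f6, Tdrd5 and Sycp2 lie higher in 4n cells and Prm1, Tnp2 and Akap4 higher in 1n cells in all 3 genotypes.

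The tagged gene Piwil1 (ENSMUSG00000029423, chromosome 5, 128779588 to 128832538 on GRCm39) was not called between lines in either population. In 4n cells it stood at 747 ± 50.6 RPM in Strep1 and 825 ± 64.6 in Strep2 against 640 ± 76.1 in WT (SD, n = 3), with limma adjusted p of 0.725 and 0.194. In 1n cells it stood at 29.8 ± 2.65 and 32.9 ± 2.42 against 35.8 ± 7.23 RPM, with limma adjusted p of 0.392 and 0.803. The authors' deposited table gave Piwil1 in 4n Strep2 a log2 fold change of 0.24 with an adjusted p of 0.0327, and in the other comparisons with WT adjusted p of 0.329, 0.896 and 0.939.

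Strep1 differed from WT in a set of genes with large folds. In 4n cells, compared within one library series, Klb, a co-receptor for fibroblast growth factors, rose from 1.40 ± 0.507 to 36.1 ± 2.99 RPM, and H2-Ab1, a chain of the class II major histocompatibility complex, from 1.62 ± 0.358 to 22.8 ± 2.28. Niban1 fell from 39.9 ± 2.95 to 0.406 ± 0.0736 RPM, a log2 fold change of -6.38 (SE 0.12, limma adjusted p = 3.21e-09). Foxp4, Lgi2, Rrp9 and Letm1 also rose, with log2 fold changes from 1.57 to 2.63, and Col6a4, Afap1, Rpl29, Usp46 and Abhd14a fell, from -1.11 to -2.89. Outside the naming rule, and named here after its value was seen, Kcnip4 fell with a log2 fold change of -6.23. Of 18463 genes 160 were called, 99 higher and 61 lower. Rpl29 and class I histocompatibility genes have close copies, so their values are uncertain. The authors' deposited table called 233 genes, and all 111 called in both had the same sign.

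In 1n cells Klb again rose, from 1.72 ± 0.375 to 30.5 ± 2.20 RPM, and H2-Ab1 from 3.37 ± 0.770 to 30.1 ± 1.35. Hmcn1, Pccb, Tmem37 and Lgi2 rose with log2 fold changes from 2.40 to 3.20, and Gm50222 rose by 4.96. Niban1 fell from 22.9 ± 1.85 to 0.155 ± 0.0363 RPM, and Kcnip4, Parp3, Rpl29, Col6a5 and Nfxl1 fell with log2 fold changes from -1.33 to -4.18. Of 20988 genes 266 were called, 137 higher and 129 lower. The authors' deposited table called 453, and the 203 called in both had the same sign. For Niban1 that table gave a log2 fold change of only -0.086 (SE 0.17, authors' adjusted p = 9.11e-14) in 1n cells, and -6.94 in 4n cells. A fold below its SE does not go with so small a p. That deposited fold may therefore not be a like measure to the limma fold. Genotype and library series coincide here, and the count went down to 157 without Strep1 replicate 1, 162 without replicate 2 and 168 without replicate 3, and to 177 without WT replicate 1. Between populations 82 genes were called in both, 81 of them with the same sign, where independent lists would share 0.912.

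The called genes of Strep1 lay close together on some chromosomes. With calls less than 10 Mb apart joined and at least 4 calls required, settings chosen after the positions were seen, 127 of the 160 genes called in 4n cells fell in 9 stretches. The longest were on chromosome 5 (33877387 to 87998377, 32 calls), chromosome 9 (73009752 to 107558698, 36 calls), chromosome 1 (118249564 to 139512521, 18 calls) and chromosome 17 (25352356 to 36452650, 14 calls, 14 higher), the last holding H2-Ab1, H2-D1 and H2-K2. Piwil1 lies outside them. The short stretches on chromosome 3 and chromosome 11 hold copies of the small RNAs U1 and U3, which share reads, and 0 calls in 1n cells.

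**Figure D2:**
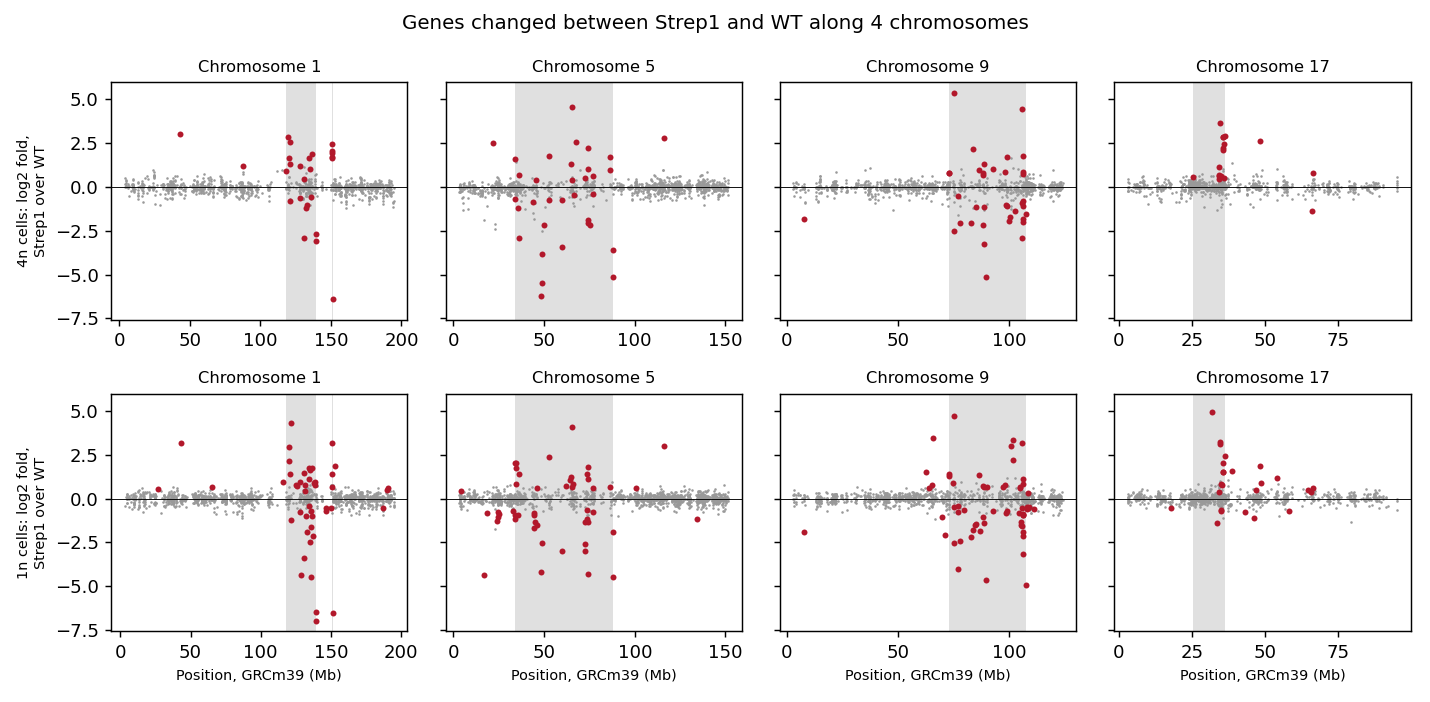
Log2 fold change of Strep1 over WT for genes along chromosomes 1, 5, 9 and 17 (GRCm39, Mb), in 4n cells above and 1n cells below. Red points are called genes, grey points other tested genes, and grey bands the stretches defined from the 4n calls. On chromosome 17 the 14 genes called in the band in 4n cells are all higher in Strep1.

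Limma called fewer genes against WT in Strep2 than in Strep1, but in 4n cells the authors' deposited table called more (384 against 233), and so did an unadjusted p under 0.05 in limma (2726 against 1359). In 1n cells, within one library series, the chemokine gene Ccl28 fell from 10.9 ± 1.39 to 1.25 ± 0.0763 RPM (SD, n = 3), a log2 fold change of -3.04 (SE 0.14, limma adjusted p = 2.1e-08), and Dipk1a, Crlf2, Tmem267 and Mtrex also fell. The kinase gene Map3k1 rose from 3.59 ± 0.390 to 11.8 ± 2.60 RPM, and Tmed6, Chfr, Paqr8 and Hmgcs1 rose with log2 fold changes from 0.57 to 0.97. In 4n cells Ccl28 also fell, from 12.4 ± 2.29 to 0.143 ± 0.0581 RPM (log2 fold change -5.79, limma adjusted p = 1.88e-06), as did Dipk1a, from 4.90 ± 0.241 to 0.634 ± 0.104 RPM (-2.87), both below the level set for naming in 4n cells and named there after their values were seen. Among genes above that level Zfp131 fell from 35.3 ± 2.75 to 18.9 ± 1.49 RPM, with Terf1, Mtrex, Tmem267 and Hjurp also lower, and Rnf212, a factor of meiotic crossing over, rose from 2.25 ± 0.144 to 5.89 ± 1.05. Rmrp, the RNA of RNase MRP, rose by a log2 fold change of 1.12 under both of its Ensembl identifiers, which hold identical values, and Rnu12, Plod3 and Tmed6 rose by 1.17, 0.95 and 0.89. In all, limma called 21 of 20988 genes in 1n cells (9 higher, 12 lower) and 28 of 18463 in 4n cells (14 higher, 14 lower). The authors' deposited table called 115 and 384, with 18 and 24 called in both. The 4n count went down to 12, 12 and 9 without Strep2 replicate 1, 2 and 3 and to 14, 11 and 11 without WT replicate 1, 2 and 3, and the 1n count to 12, 11 and 11 without Strep2 replicate 1, 2 and 3 and to 13 without WT replicate 1. Without further scaling of the RPM values the 4n split was 10 higher and 6 lower.

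The lines also differed from each other. In 1n cells 266 genes were called between Strep1 and Strep2 (117 higher in Strep1) and in 4n cells 170 (98 higher). Without 1 library the first count went to 176 and 174 (Strep1 replicate 1 or 3) or 177 (Strep2 replicate 2), and the other to 110 and 106 (Strep1 replicate 1 or 2). Klb, H2-Ab1 and Niban1 were again among the largest, with log2 fold changes of 3.57, 3.54 and -6.71 in 1n cells and 3.85, 3.90 and -6.31 in 4n cells. Ccl28 and Map3k1 differed in 1n cells by 2.41 and -1.52, and Foxp4 in 4n cells by 2.85. Both lines shared 3 calls of one direction in 1n cells (Gm40603, Tmed6 and Ccl28, named after their values were seen), where independent lists would share 0.133 and simulated unchanged groups against the same WT libraries shared 0.08 on average and at most 2. In 4n cells they shared 3 in one direction (Rmrp under both identifiers and Rnu12) and 1, Gm47283, in opposite directions, against 0.121 and 0. Part of this excess may come from the shared WT libraries, which are too few to split. Unchanged groups may call few genes, and the sizes of the simulated lists are not given. Their overlap is therefore no firm benchmark for the real lists. Log2 fold changes of the lines correlated at 0.39 in 1n and 0.53 in 4n cells across genes, against 0.50 in simulations of both, and their covariance was 0.0295 against 0.0164 and 0.050 against 0.0204.

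Gene lists moved little between lines. Camera with the preset correlation called 11 of 56 list tests against WT. With an estimated correlation it called 0 here, and 0 for WT 1n against 4n cells, where 29 of 31 sperm tail genes rose. A call that did not hold there therefore does not show that a list is unchanged. Round spermatid and acrosome genes were called as higher in both lines in 1n cells (median log2 fold change 0.16 in Strep1 and 0.14 in Strep2, adjusted p = 7.64e-05 and 2.63e-05), with 0 of 32 called singly, and neither call held (adjusted p = 0.555 with an estimated correlation for both). Sertoli cell genes were called as lower in 1n cells of both (medians -0.28 and -0.33, adjusted p = 0.00244 and 0.00124), with 0 of 12 called over all genes and 1 and 2 lower adjusted over the list alone, and Clu at 3.60 ± 0.852 against 5.94 ± 1.07 RPM in Strep1, and neither call held (adjusted p = 0.555 with an estimated correlation for both). Mitochondrially encoded genes were called as higher in 4n cells (medians 0.68 and 0.36, adjusted p = 1.16e-11 and 0.00422), with 0 of 15 called over all genes and 12 and 0 adjusted over the list alone. These calls did not hold (adjusted p = 0.555 and 0.971 with an estimated correlation), and mt-Nd3 stood at 64.4 ± 13.5 RPM in 4n Strep1 against 34.01 ± 5.64 in WT, while the libraries of mt-Co1, named after its values were seen, overlapped (2733 to 4731 against 2015 to 2832 RPM). Meiotic genes were called as higher in 4n cells of both lines (medians 0.07 and 0.20, adjusted p = 0.0402 and 0.000132), with 0 and 1 of 33 called, the 1 being Rnf212, and neither call held (adjusted p = 0.971 and 0.555 with an estimated correlation). In 4n Strep2 the piRNA pathway (median 0.14, adjusted p = 0.0114, 1 of 28 called, Adad2) and spermatogonial genes (median 0.28, adjusted p = 0.0271, 0 of 12 called and 3 adjusted over the list alone) were called as higher, again not with an estimated correlation (adjusted p = 0.971 and 0.555 with an estimated correlation). The macrophage and blood list was called as higher in 4n Strep1 (adjusted p = 0.0262, and adjusted p = 0.555 with an estimated correlation), with H2-Ab1 the 1 called of 4 members. The remaining 45 tests, which cover every test of the Leydig, peritubular, elongating spermatid, sex chromosome, p53, heat shock and interferon lists, had adjusted p of at least 0.0919, and 14 of them had a median, mean and test that differed in sign. Akap3, of the sperm tail, was the 1 member of the elongating spermatid list called in 1n Strep1 (log2 fold change 0.33). Of the 11, fry called only the macrophage list in 4n Strep1 (adjusted p = 0.00604).

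Repeats were tested over subfamilies. In 1n Strep1 22 of 3010 were called, 21 lower and 1 higher, of which the 5 of smallest p were all short simple repeats at or below 1.37 RPM. In 4n Strep1 5 of 3280 were called, 4 lower and the small nuclear RNA U1 higher (86.7 ± 10.1 against 50.1 ± 1.17 RPM), with the endogenous retrovirus MuRRS-int lower (9.63 ± 1.52 against 28.4 ± 1.91 RPM, limma adjusted p = 0.00933). In Strep2 limma called 0 in either population, with 637 in 1n and 184 in 4n cells at an unadjusted p under 0.05. The median log2 fold change over repeats, relative to all features, was -0.24 in 1n Strep1 (0.00 when scaled over repeats alone), -0.22 in 1n Strep2, -0.22 in 4n Strep1 (0.02 when scaled over repeats alone) and -0.28 in 4n Strep2, and the L1Md and IAP families, young LINE-1 elements and retroviruses, had medians from -0.29 to -0.53, with fry adjusted p of 0.286 to 0.683. Summed IAP signal went the other way in 4n Strep1, at 705 ± 108 against 661 ± 35.3 RPM (exact permutation p = 0.6), and summed L1Md signal there was 3862 ± 889 against 5258 ± 1541 RPM (exact permutation p = 0.3). In 1n Strep1 the L1Md and IAP sums were 0.713 and 0.793 of WT (exact permutation p = 0.1, the smallest possible, for each). In Strep2 they were 0.821 and 0.905 of WT in 1n cells (exact permutation p = 0.4 for each). In 4n Strep2 they were 0.762 and 0.877 (exact permutation p = 0.5 for each). Summed repeat signal was 77662 ± 4463 RPM in 1n Strep1 and 80134 ± 7543 in 1n Strep2 against 93187 ± 6891 in WT (SD, n = 3, exact permutation p = 0.1, the smallest possible, for each). In 4n cells it was 101110 ± 13410 RPM in Strep1 and 99032 ± 17615 in Strep2 against 111680 ± 13531 in WT (exact permutation p = 0.5 and 0.4). Single 4n libraries stood apart here, with Strep2 replicate 2 at 81311 RPM of repeats (99245 and 116540 in the others of its group), Strep1 replicate 3 at 85720 (107330 and 110280) and WT replicate 2 at 126680 (100400 and 107950). In 1n cells WT replicate 3 stood apart, at 101130 RPM (89628 and 88804 in the others of its group). Strep2 replicate 1 in 1n cells, at 88584 RPM, lay close to those other WT libraries. Antisense repeat signal in 1n cells was 0.841 of WT in Strep1 and 0.849 in Strep2 (exact permutation p = 0.1 for each) and in 4n cells 0.895 and 0.8704 (exact permutation p = 0.5 and 0.4). In 1n cells the sense share of all signal was 86.4% ± 0.961 and 86.3% ± 0.837 against 84.5% ± 0.997 in WT (SD, n = 3). The 22 calls went down to 5 when libraries were scaled over repeats alone and to 0 without the filter, and became 5, 4 and 5 without Strep1 replicate 1, 2 and 3 and 115, 4 and 3 without WT replicate 1, 2 and 3. In 4n Strep1 the 5 calls went to 3 without Strep1 replicate 2 and to 1, 3 and 2 without WT replicate 1, 2 and 3. In 1n Strep2 1 repeat was called without WT replicate 3.

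The piRNA cluster transcripts, from which pachytene piRNAs are made, were far more abundant in 4n than in 1n cells. Their sum was 49466 ± 1238 RPM in WT 4n against 5978 ± 118 in WT 1n cells (SD, n = 3), 8.27 times higher (exact permutation p = 0.1, the smallest possible), and 196 of 210 loci were called, 176 lower in 1n cells. In Strep1, within one series, the sum was 8.50 times higher in 4n cells. The median log2 fold change of the WT loci was -2.66 relative to all RNA, and 0.07 when scaling over clusters alone centred the loci by construction. A locus on chromosome 9 (54114458 to 54157108) fell from 1181 ± 20.0 to 10.6 ± 0.663 RPM. Between lines the sums differed by less than the spread in 1n cells. In 4n Strep2 the sum was 46887 ± 1615 RPM (exact permutation p = 0.1) and 22 loci were called, 17 lower and 5 higher, among them a locus on chromosome 18 (67162518 to 67199532) at 1061 ± 93.4 against 1410 ± 133 RPM and one on chromosome 2 (92371487 to 92439490) at 1196 ± 17.4 against 1613 ± 33.9 RPM. In 1n Strep1 2 loci were called, pi-Ppp1r12b (52.9 ± 7.04 against 25.01 ± 0.714 RPM, higher), which lies in the longer chromosome 1 stretch, and a locus on chromosome 10 (85584426 to 85617615, lower), and the count went to 1 without any 1 of the Strep1 libraries or WT replicate 1 or 2. In 1n Strep2 and 4n Strep1 limma called 0, with 39 and 18 at an unadjusted p under 0.05. In 1n Strep2 6 were called with the replicate block (3 higher), 4 with all 18 libraries (3 higher) and 3, all higher, when scaled over clusters alone, and in 4n Strep1 3 with all 18 libraries (2 higher). Without Strep2 replicate 1 in 1n cells 1 was called, and in 4n cells 2 without Strep1 replicate 1 and 2 without WT replicate 1. The 22 loci became 41 without Strep2 replicate 1, 6 without Strep2 replicate 3, 11 without WT replicate 1 and 13 without WT replicate 2. Between Strep1 and Strep2 4 loci were called in 1n and 12 in 4n cells, the latter going to 52 without Strep1 replicate 3, to 0 without Strep1 replicate 1 or 2 or Strep2 replicate 3, and to 1 without Strep2 replicate 1, and the former to 1 without Strep1 replicate 1 and 2 without Strep1 replicate 3, Strep2 replicate 2 or Strep2 replicate 3.

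MIWI purified from Strep1 testes carried mostly piRNAs from these clusters. Pachytene clusters took 87.05% ± 1.56 of the sense signal (SD, n = 5, range 84.96% to 88.48%), repeats 4.41% ± 0.0684, protein-coding genes 3.99% ± 1.28, long non-coding RNA 3.19% ± 0.0823, structural RNA 0.941% ± 0.279 and microRNA 0.0777% ± 0.0129. Antisense signal was 85.1% ± 0.751 repeats, which held 99190 ± 6952 RPM on that strand against 31120 ± 1970 RPM on the sense strand. The 10 strongest features were all clusters and together held 39.7% of the sense signal, led by the loci on chromosome 18 (67162518 to 67199532) at 58020 ± 11360 RPM, chromosome 2 (92371487 to 92439490) at 32910 ± 1928 and chromosome 5 (149713537 to 149755055) at 31470 ± 5955, and 0 of them were piRNA pathway genes. Pairs of the 5 libraries correlated across 55358 genes at Pearson 0.922 to 0.983 and Spearman 0.814 to 0.846, and genes are not independent replicates. No control purification belongs to the labelled samples, so background binding was not measured. Counting both strands together the cluster share was 74.8%.

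In the slicing assay, tagged MIWI and its piRNAs were given targets matched fully to piRNAs (Perfect pool) or carrying mismatches opposite piRNA bases 10 and 11 (Bulge pool). RNA starting at position -9, where a cut opposite those bases would leave a new 5-prime end, was abundant in the Perfect pool at 19670 and 15930 RPM and scarce in the Bulge pool at 79.55 and 45.15 RPM. The means of 17800 and 62.4 RPM differ 285-fold, and the exact two-sided permutation p is 0.33, the smallest that 2 against 2 libraries allow. As a share of plus-strand signal the values were 18.5% and 11.8% against 0.298% and 0.229%, a ratio of 57.5, and the ratio was 140 for ends within 1 nt of the position. Per 100 full-length targets there were 70.05 and 26.62 such ends in the Perfect and 1.88 and 2.60 in the Bulge libraries, a ratio of 21.6, with the full-length target itself at 43960 ± 22460 against 2987 ± 1774 RPM (SD, n = 2), a ratio of 14.7. Ends at position -33, the start of the intact 54 nt target, stood at 61290 ± 26420 RPM in the Perfect and 17440 ± 2808 in the Bulge pool (SD, n = 2), and position -3 at 4290 ± 850 and 22.0 ± 26.5. RNA ending just before position -9, the other product of such a cut, stood at 2090 ± 559 and 297 ± 0.508 RPM. After position -33 the Bulge libraries were highest at position 3, at 1455 and 581 RPM against 24.0 and 17.5 in the Perfect libraries. Minus-strand reads ending at position 0 bear on the inferred positions in the Perfect pool alone (72.0% of minus-strand signal against 0.269%). Whether the same positions hold for the Bulge pool was not tested. On the log2(RPM + 1) scale, profiles over 40 positions correlated at Pearson 0.990 between the Perfect and 0.862 between the Bulge libraries, and between -0.0507 and 0.109 across pools. On the RPM scale, where position -33 is the highest in all 4 libraries, the values were 0.968, 0.998 and 0.888 to 0.977. RPM is set against each library's total, which is not stated, and the pools differ 5.20-fold in plus-strand signal.

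**Figure D3:**
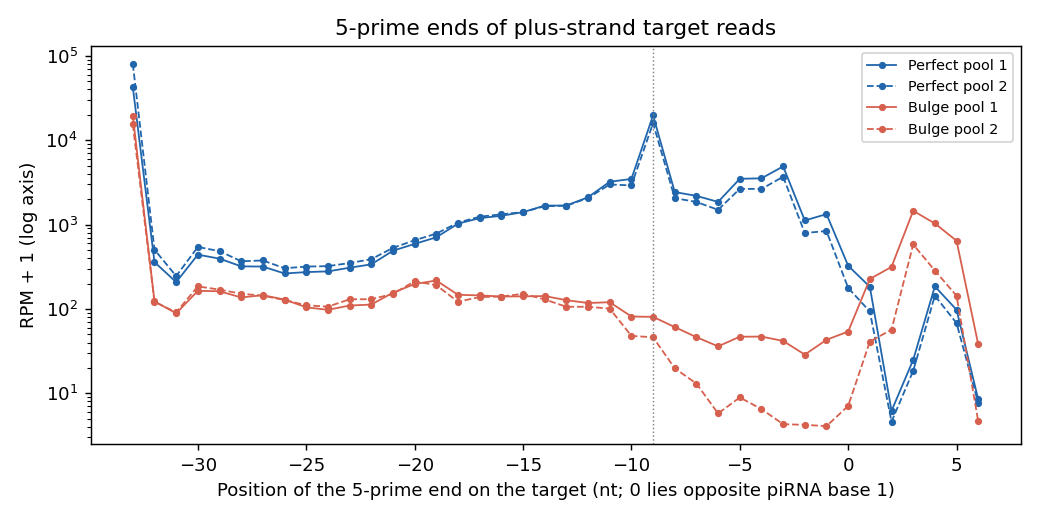
RPM + 1 (log axis) of plus-strand reads by the position of their 5-prime end on the target, in nt, for the 4 slicing libraries. Blue lines are the Perfect and red lines the Bulge pool, solid replicate 1 and dashed replicate 2, and the dotted line marks position -9, where the Perfect libraries stand at 19670 and 15930 RPM.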

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

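Of the tests below, those on chromosomal stretches, on library series for the repeats and on piRNA clusters as a kind of feature were chosen only after the result was seen.

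Genes called in Strep1 stand together on chromosomes in both populations. A candidate explanation is that Strep1 carries chromosome segments that differ from WT by descent, since 53.05% of the genes called in 1n cells lie in the stretches drawn from the 4n calls, against 6.07% of tested genes (permutation test by circular shifts of the calls, p = 1e-04, the smallest 10000 draws can give), and 92 of 110 genes keep their sign. Because genes called in both populations raise that share by themselves, it was recomputed over the 180 genes called in 1n but not in 4n cells, and 40.56% of these lay inside (same permutation test, p = 0.0017). A difference between library series is argued against by the longer stretches found in the 4n libraries, all of one series. The 9 stretches include the U1 and U3 copies, and a chromosome 4 stretch that reaches 4 calls by counting Rmrp under both identifiers. Of the 4n calls inside the 9 stretches, 59.84% were higher in Strep1. This argues against reads lost at sequence variants in Strep1 for those calls. It cannot exclude reads lost at variants in WT, which would also make Strep1 higher. The segments themselves were not seen, and the source of the difference was not tested. In Strep2, 3 stretches with 12 of its 20 placed 1n calls rest on a lower minimum of 3 calls. They held 60% of 1n calls against 0.477% of tested genes (same permutation test, p = 1e-04), but 8 of the 12 were also called in 4n cells. Of the 9 genes called in 1n but not in 4n cells, 4 lay inside (same permutation test, p = 0.0018). At a minimum of 4, 1 stretch with 7 calls remained, 35% against 0.231% (same permutation test, p = 8e-04). It held 2 of the 9 genes called in 1n but not in 4n cells (same permutation test, p = 0.0056). That stretch lies on chromosome 13 and holds Ccl28, Mtrex, Tmem267 and Zfp131. At the minimum of 3 there is also a stretch on chromosome 5 (108053220 to 110615121) that holds Dipk1a and Rnf212. Piwil1 lies on that chromosome but outside the stretch, from 128779588.

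Repeats were lower in 1n Strep1, with 21 subfamilies called lower (10 called on the antisense strand, 4 higher and 6 lower), and summed antisense repeat signal was lower too, at 0.841 of WT in Strep1 and 0.849 in Strep2 (exact permutation p = 0.1, the smallest possible, for each). Of the 1n libraries WT replicate 3 was the highest, at 118320 RPM of antisense repeats (102580 and 101490 in the others of its group). Scaling the libraries over repeats alone, which centres the repeats by construction, left 4 of lower level. This fall cannot tell a shift of all repeats against genes from changes of single subfamilies. Leaving out any 1 library other than WT replicate 1 also cut the 22 calls, to between 3 and 5. The median log2 fold change of the 22 called went from -0.59 (quartiles -1.12 and -0.54) to -0.33 (quartiles -0.89 and -0.28), so the calls ended with smaller folds. The median over all 3010 repeats was -0.22 in 1n Strep2, of the series of WT, against -0.24 in 1n Strep1, which goes against library series as its source. It does not exclude it, because the median level of repeats per library in Strep1, of the other series, minus that in Strep2 was -0.026 with a 95% interval from -0.29 to 0.24, which holds both 0 and the difference of -0.25 from WT (95% interval -0.52 to 0.02). The 21 called lower had a median of -0.59 against WT, -0.30 against Strep2 and -0.33 for Strep2 against WT, where the shared WT libraries chose them. A difference between the lines was not tested apart from these.

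In 4n Strep2 22 piRNA cluster loci were called, 17 of them lower. With scaling over clusters alone 13 of the 22 stayed called, between the bounds set for a shift of all clusters against genes and for changes of single loci. The median log2 fold change of the 22 went from -0.41 to -0.31, and that over all clusters from -0.115 to -0.012. The 13 that stayed and the 5 called higher argue against a common fall as the only source. For the other calls a shift and single changes cannot be told apart. A biological difference between Strep2 and WT stays open and untested.

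Other groupings of the same libraries were tried for each count. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, so only the real and the highest other count are given. Genes called were 266 and 0 for 1n Strep1 against WT, 21 and 0 for 1n Strep2, 266 and 0 for 1n Strep1 against Strep2, 160 and 0 for 4n Strep1, 28 and 0 for 4n Strep2, and 18857, 18914 and 19027 against 0 for 1n against 4n cells, each with 1 split as large, the real one. For 4n Strep1 against Strep2 2 splits reached the real 170 and the highest other gave 375, which points to a structure of these samples other than genotype. That split set Strep2 replicates 2 and 3 with Strep1 replicate 3 against the other 3 libraries, and gave the 89 clusters below as well. Strep2 replicate 2 and Strep1 replicate 3 held 731240 and 709290 RPM in genes, against 599160 and 666650 in the others of Strep2 and 623460 and 628570 in those of Strep1, and all 4n counts and lists with either line include them. Repeats were 22 and 1, 0 and 28, 5 and 0, and 0 and 0 in 1n Strep1, 1n Strep2, 4n Strep1 and 4n Strep2, with 1, 10, 1 and 10 splits as large. Clusters were 2 and 7, 0 and 8, 0 and 0, and 22 and 0 in the same order, with 2, 10, 10 and 1 splits as large, 4 and 1 (1 split) and 12 and 89 (2 splits) for Strep1 against Strep2 in 1n and 4n cells, and 196 and 0 (1 split) for WT populations. Lists called were 2 and 6, 2 and 4, 3 and 5, and 4 and 4, with 10, 10, 6 and 3 splits as large, and 7 and 10 for WT populations with 6. List calls at the preset correlation were thus no more than the highest of other groupings. Other splits mix both groups, so they can keep part of a real difference. For WT populations they gave up to 10 lists, although 29 of 31 sperm tail genes rose in 1n cells. These list counts therefore cannot tell a real difference from another grouping.

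A test of the difference between populations called 44 genes for Strep1 and 10 for Strep2 at the FDR of 0.05. In 100 drawn splits 8 gave as many as the 44 of Strep1, the highest being 200, so chance is not excluded. The 44 went to 75 with the pseudocount of 0.5 and to 27 with 0.02. For Strep2 1 split gave as many as the 10, the real one, with a highest other of 9. That share under 0.05 rests on a margin of 1 gene. The 10 went to 4 with the pseudocount of 0.02 and to 6 without Strep2 1n replicate 1 or 2. No split counts are given for those fits, so these counts cannot be set against the 9. For Strep1, where the 1n difference coincides with library series, the log2 difference of differences (1n minus 4n) was 3.10 for Afap1, 2.35 for Col6a4, 2.13 for Usp46, 2.12 for Kcnip4, 1.39 for Arpc5, 1.27 for Cfap99, -1.52 for Nfxl1, -1.17 for Plod3, -0.97 for Pik3r4 and -0.83 for Zfp949. Afap1 stood at 2.06 ± 0.565 RPM in 4n Strep1 and 14.9 ± 1.76 in 4n WT, but at 32.5 ± 3.32 and 28.4 ± 8.17 in 1n cells. For Strep2 it was 2.80 for Ccl28, 0.93 for Zfp131, -1.98 for Maz and -1.23 for Plod3.

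In the purified small RNA the antisense share of clusters was 0.436% in replicate 1 against 0.303% to 0.324% in the other 4 libraries, a gap of 0.84 of the range. The threshold for such a gap is passed by chance in about 1 of 20 groups, the shares of 14 classes and the levels of 10 features were examined, and replicate 1 has a library name of another series than the rest. The minus strand of the slicing libraries, which the comparison of targets does not use, held 161700 ± 19120 RPM in the Perfect and 7811 ± 194 in the Bulge pool (SD, n = 2), and 72.0% of it in the Perfect pool ended at position 0, against 0.269%.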

How the results depend on the processing

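No named gene turned its direction past the threshold. The fits of pseudocounts 0.5 and 0.02, of unscaled RPM, of clusters, of the all-feature correlation, of the slicing ratio per full-length target and of slicing profiles without log were chosen after seeing the data, the others before. No cause was tested unless named. The planned edgeR and DESeq2 tests were not run because the values are not counts.

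Fitting the 2 groups compared alone (fewer samples) gave 174 genes in 1n Strep1, 1 cluster there and 5 clusters for 4n Strep1 against Strep2. All 18 libraries gave 55 genes in 4n Strep2 and 4 and 3 clusters in 1n Strep2 and 4n Strep1. The authors' deposited adjusted p gave 453, 115 and 384 genes in 1n Strep1, 1n Strep2 and 4n Strep2. Requiring 2-fold changes gave 127, 13, 148, 16 and 113 genes in 1n Strep1, 1n Strep2, 1n Strep1 against Strep2, 4n Strep2 and 4n Strep1 against Strep2. Without the filter there were 13 genes in 1n Strep2 and 15 in 4n Strep2, 0 repeats in 1n Strep1 and 3 in 4n Strep1, and 1, 9 and 1 clusters in 1n Strep1, 4n Strep2 and 4n Strep1 against Strep2. Unscaled RPM gave 16 genes in 4n Strep2 (10 higher, 6 lower), 1 cluster in 1n Strep1 and 0 for 4n Strep1 against Strep2. Scaling over repeats left 5 and 2 repeats in 1n and 4n Strep1, antisense reads 10 in 1n Strep1 (4 higher, 6 lower), and scaling over clusters gave 3 in 1n Strep2 and 0 for 4n Strep1 against Strep2. For genes differing between populations, the pseudocount of 0.5 gave 75 in Strep1 and that of 0.02 gave 27 in Strep1 and 4 in Strep2. With an estimated correlation 0 list tests of lines and 0 of WT populations were called, and with fry 1 and 13. Both strands together put the cluster share at 74.76%, and all features put the lowest small RNA correlation at 0.9461. The slicing ratio was 57.51 as a share, 140.4 over a window, 57.51 over the median of other positions and 21.57 per full-length target, and RPM without log put the lowest slicing profile correlation of replicates at 0.9682.

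Replicate numbers did not pair the samples: correlations of deviations between libraries with the same number ran from -0.452 to 0.457, and in no comparison did all pass 0.1. With the replicate block there were 16 genes in 4n Strep2, 6 and 2 repeats in 1n and 4n Strep1, and 4 and 6 clusters in 1n Strep1 and 1n Strep2.

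Leaving out 1 library at a time gave these ranges of genes: 157 to 334 in 1n Strep1, 11 to 21 in 1n Strep2, 174 to 271 for 1n Strep1 against Strep2, 117 to 139 in 4n Strep1, 9 to 14 in 4n Strep2, 106 to 168 for 4n Strep1 against Strep2, 18311 to 18485, 18282 to 18601 and 18368 to 18715 for WT, Strep1 and Strep2 populations, and 31 to 64 and 6 to 11 for differences between populations in Strep1 and Strep2. Repeats ran from 3 to 115, 0 to 1, 1 to 4 and 0 to 0 in 1n Strep1, 1n Strep2, 4n Strep1 and 4n Strep2. Clusters ran from 1 to 3, 0 to 1, 0 to 2 and 6 to 41 in the same order, 1 to 6 and 0 to 52 for Strep1 against Strep2 in 1n and 4n cells, and 192 to 197 for WT populations. The cluster share ran from 86.69% to 87.57% and the slicing ratio from 223.7 to 394.2, highest without Bulge replicate 1. The 52 clusters came without 4n Strep1 replicate 3, and 0 without 4n Strep1 replicate 1 or 2 or Strep2 replicate 3. Of the settings run for named genes, 8683 gave the same side of the threshold, 198 lost the call and 20 gained it.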

Other observations

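The tests by repeat class below were chosen after the data were seen. Repeat classes also differed between populations. In WT 35 of 37 SINE subfamilies were called lower in 1n than in 4n cells and 0 higher, with a median log2 fold change of -0.76 (fry adjusted p = 0.018 against no change), and simple repeats had 1220 of 2513 lower and 450 higher (median -0.50, fry adjusted p = 0.0127 against no change). The median over all repeats was -0.44, and no test compared a class with the others. The L1Md and IAP families had medians of -0.02 and 0.00 and fry adjusted p of 0.993 for both. Strep1, within one library series, gave medians of -0.87 for SINE and -0.56 for simple repeats.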
